A study of Mus musculus with 2 samples.

How the data were processed

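The study measured H3K4me3 by chromatin immunoprecipitation and sequencing in forebrain tissue of mouse embryos at 11.5 days, in 2 biological replicates that form 1 group. Replicate 1 pooled 109 embryos and replicate 2 pooled 88, of both sexes, and the library fragments were selected in a range of 300 to 500 bp, per the labels. The labels give each library a biological replicate number, so the replicates are separate pools of tissue.

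The authors deposited 4 peak lists in narrowPeak format on mm10. Per the text deposited with them, each replicate's list was derived from that replicate's alignments and 2 further inputs that it does not describe. Another list came from both replicates together, and the replicated list was derived from the other 3. The aligner, the peak caller, its threshold and the rule for calling a peak replicated are not given in the sources used here. The signal values per peak were deposited by the authors, and how they were scaled is not given in the sources used here, so they were used only within one list, to rank, describe or filter peaks and to compare genes of that list. The −log10 q value of each peak was likewise deposited by the authors. The deposited lists include weak peaks: 8.05% of replicate 1 peaks, 8.39% of replicate 2 peaks and 2.12% of replicated peaks had a −log10 q below 2. Every replicated peak was found in the pooled list at the same start and end. All 19544 pooled peaks that shared at least 50% of either peak's length with a peak of both replicates were in the replicated list, and these made up 91.6% of it. A control experiment that the labels name was not analysed here. Without read counts the depth of each library is unknown, so no interval or detection floor that needs it is given, and a gene without a peak is one with no deposited peak, which does not show that the mark was absent.

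The replicated list was the main list, with each replicate's own list beside it. Positions were compared with GENCODE annotation vM21 on GRCm38, the assembly that mm10 names, over 21 chromosomes, with 55413 genes, 21938 of them protein-coding, and 132721 distinct gene and TSS pairs. Coordinates are printed counting from 1. A gene was called marked when a peak overlapped the window of 1000 bp either side of any of its annotated TSSs. Domains were made by merging peaks at most 1000 bp apart. A gene's domain was the widest with a peak in its window, and its height was the highest signal value of a peak there. Peaks over 5000 bp from every annotated TSS were described separately. The observed to expected CpG ratio was computed from the GRCm38 sequence within 500 bp either side of each gene's outermost 5′ end. Overlap of peaks was counted from 1 shared bp, and shuffled backgrounds moved peaks at random within their chromosome 100 times. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.

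Before the data were examined, 21 gene lists, the tests and the alternatives were fixed. The lists were forebrain patterning transcription factors, ventral telencephalon and GABAergic genes, dorsal telencephalon and glutamatergic genes, neural progenitor genes, postmitotic neuron genes, mature astrocyte and oligodendrocyte genes, brain signalling centre genes, and midbrain, hindbrain and spinal cord transcription factors. Further lists were Hox genes, mesoderm and endoderm transcription factors, erythroid genes, macrophage and microglia genes, endothelial and pericyte genes, mesenchyme and meninges genes, and differentiated liver, muscle, pancreas and skin genes, a list that also holds genes of kidney and lung. The remaining lists were housekeeping, cell cycle, germline, pluripotency and imprinted genes and olfactory and vomeronasal receptor genes. Of the members, Ahsp was not in the annotation. Some lists share members: 6 of the 32 forebrain patterning factors were also in another list, as were 4 of the 20 dorsal and 2 of the 20 ventral genes. The share of marked genes in each list was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, adjusted by Benjamini and Hochberg's method over the 21 lists. The median width and height of marked members were compared with those of all other marked genes by a two-sided permutation test with 100000 resamples, adjusted over the 18 lists with at least 5 marked members. Adjusted p-values under 0.05 are called past the threshold. No test across samples was possible with 2 samples of 1 group, and values of the replicates' own lists are given as mean ± SD (n = 2).

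The genes named in the text were chosen by a rule fixed beforehand. It takes the 20 widest domains that also lie in the widest 5% of each replicate's list, with genes that share a domain counted as 1 entry. For each gene list it takes the 3 marked genes with the widest domains and up to 3 unmarked genes in alphabetical order. It also takes the 5 replicated peaks of highest signal value over 5000 bp from a TSS, and for each replicate the 5 genes of highest signal value that the other replicate did not mark. Other genes are named only where the text says that they were chosen after their values were seen, as for the full naming of counts of 5 or fewer.

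Both tests were checked on simulated data before use. In 200 random lists of 24 marked genes whose widths were multiplied by 1.25, 1.5 or 2, the width test gave p below 0.05 in 53.5%, 95.5% and 100% of lists, and in 7% of lists left as they were. In 200 random lists of 24 genes simulated at a share of 85% or 95% marked, Fisher's test did so in 55% and 98.5%, and in 4.5% at the share of all genes.

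Alternatives fixed beforehand were a −log10 q of at least 2 or of at least 10, and the 50% of each list with the highest signal values. They also included an overlap of 50% of a peak's own length or of both peaks, no merging or merging at up to 3000 bp, and TSS windows of 500 or 2000 bp. Further ones were only the outermost TSS of each gene, each replicate's own list or the pooled list in place of the replicated list, and leaving out genes with a shared domain. The lists were also set against 10000 random lists of other genes matched on decile of CpG ratio. The two-sided p then counts random lists at least as extreme as the observed one, with a smallest value of 0.0002. For all CpG-matched lists it is printed below as a permutation test, though no labels were permuted. Random lists matched on the number of CpGs within 5000 bp either side of the outermost TSS were added after the shares and widths of the gene lists were seen, and the test of forebrain widths against them was written before any value from such lists was seen. Peaks on scaffolds outside the 21 chromosomes were counted but entered no comparison with genes.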

Results

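Trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark that lies over active and poised promoters, was profiled by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos at 11.5 days. The tissue came from strain B6NCrl, with male and female embryos pooled. The series holds 1 group of 2 biological replicates. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos. The deposited data analysed here are peak lists on the mouse genome build mm10: 23898 peaks for replicate 1, 26087 for replicate 2, 23839 for both replicates pooled, and a replicated list of 21344 peaks. The lists give no read counts, so the depth of each library is unknown and no counting interval is given. With 1 group there was no contrast between conditions, and the design implies 3 comparisons: peaks against annotated promoters, groups of genes against all other genes, and replicate 1 against replicate 2. In all tests of gene lists below, genes and not samples were the units, so a p-value describes these peak lists and not the spread between animals. The tests treat genes as independent, which neighbours in a cluster or a shared domain may not be.

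H3K4me3 lay at the promoters of most protein-coding genes. In the replicated list, 14265 of 21938 protein-coding genes (65.0%) had a peak within 1000 bp of an annotated transcription start site (TSS) and are called marked here. The share was 65.1% ± 0.63 (SD, n = 2) over the replicates' own lists. For 2937 of the genes marked in the replicated list (20.6%), the run of peaks also covered the TSS of another protein-coding gene. Antisense RNA genes were marked at 34.3% ± 1.17 (SD, n = 2), lincRNA genes at 14.2% ± 1.30 and processed pseudogenes at 1.47% ± 0.299. Of the replicated peaks, 75.6% overlapped a TSS window, against a mean of 10.1% after 100 shuffles of the peaks within each chromosome, a 7.5-fold difference. The replicates' own lists gave 70.2% ± 4.12 (SD, n = 2). Peaks at a TSS were wider, with a median of 1645 bp against 546 bp elsewhere, and held 89.1% of all bases under replicated peaks. On the X chromosome 50.6% ± 1.34 (SD, n = 2) of the protein-coding genes were marked. On the Y chromosome 4 of 183 were marked, and these were Kdm5d, Eif2s3y, Uty and Ddx3y, named after their values were seen.

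The widest H3K4me3 domains at protein-coding TSSs included those of Pou3f3, Nr2f2, Foxg1, Dlx1 and Dlx2. A domain is a run of peaks at most 1000 bp apart, and the median domain at a marked gene was 1957 bp wide in the replicated list. The widest lay over Pou3f3, a POU-domain factor of neural progenitors and neurons (chromosome 1, 42684106 to 42714663), and measured 30558 bp, with 30720 bp ± 141 (SD, n = 2) over the replicates. Next came the nuclear receptor gene Nr2f2 (chromosome 7, 70345373 to 70370808) at 26499 bp ± 1891 and Foxg1, a forkhead factor that marks the telencephalon (chromosome 12, 49373457 to 49398143), at 25391 bp ± 4487. The Foxg1 domain also covered the TSS of Gm43517. A single domain spanned Dlx1 and Dlx2, a convergent pair of homeobox genes of the ventral telencephalon (chromosome 2, 71524774 to 71547219), at 21181 bp ± 1766. In the replicated list the merging joined peaks over Dlx1 and Dlx2, of signal value 26.4 and 32.9, through weaker peaks of 2.99, 4.22 and 3.84 between them. Lhx2, a LIM homeobox gene of the cortical primordium and eye (chromosome 2, 38338655 to 38360141), had 18286 bp ± 4781. Pax6, a paired-box factor of dorsal progenitors (chromosome 2, 105666848 to 105686859), had 20274 bp ± 4185. The progenitor factor Sox2 (chromosome 3, 34648060 to 34666286) had 18038 bp ± 209.

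The other entries among the 20 widest domains were Nr2f1 at 17128 bp ± 619 (SD, n = 2), Emx2 at 17553 bp ± 20.5, Meis2 at 15232 bp ± 2810, Otx1 at 16136 bp ± 161, Dlx6 at 13139 bp ± 5218, Pou3f2 at 15069 bp ± 5.66, Lhx5 at 15104 bp ± 2220, Zic2 at 14263 bp ± 8.49, Six3 at 14136 bp ± 715 and Otx2 at 14519 bp ± 798. Zic1 and Zic4 shared a domain of 14130 bp in the replicated list, whose width differed most between the replicates, at 11932 and 26164 bp. The 2 remaining entries were Tnrc18 at 13462 bp ± 1.41 and a domain at Skida1 and A930004D18Rik of 13298 bp in the replicated list. Replicate 1 gave both of these genes a width of 13258 bp. Replicate 2 gave Skida1 20350 bp and A930004D18Rik 9069 bp, so they did not have the same domain there. All 20 entries were in the widest 5% of both replicates' lists, as the rule for naming them required.

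**Figure D1:**
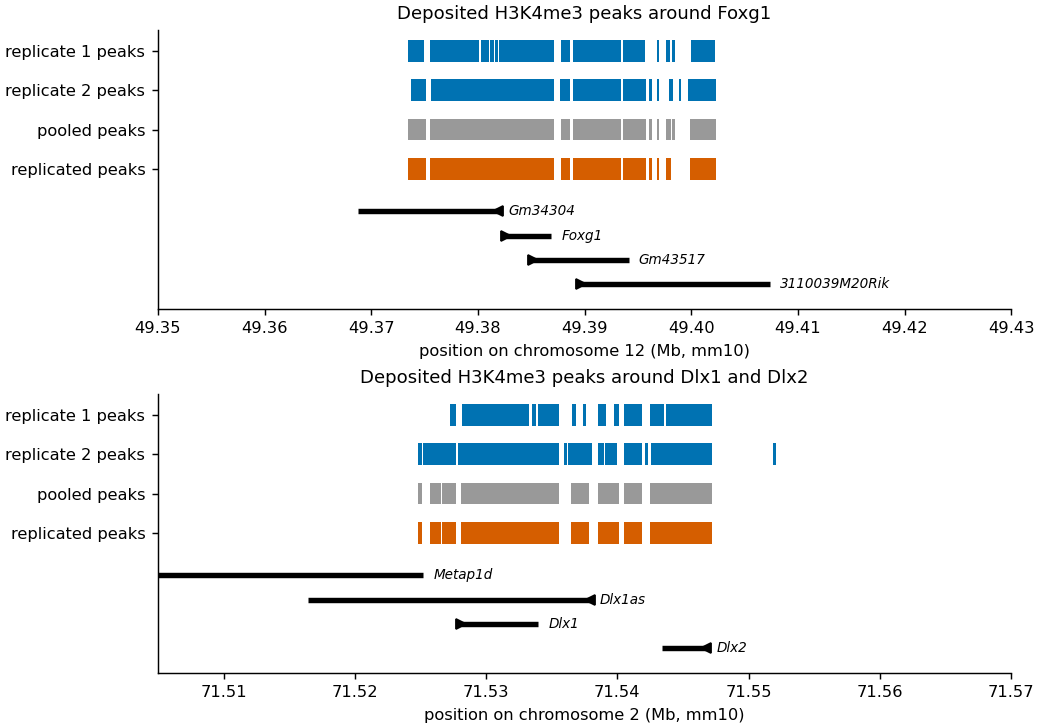
Deposited H3K4me3 peaks around Foxg1 on chromosome 12 and around Dlx1 and Dlx2 on chromosome 2. The horizontal axis is the position in Mb on mm10, each row of boxes is a peak list, and black bars are genes with an arrowhead at the TSS. Peaks of both replicates covered the Foxg1 gene and its flanks, over a replicated domain of 24687 bp, and ran through Dlx1 and Dlx2, over a replicated domain of 22446 bp. The Dlx1 and Dlx2 domain in replicate 1's own list was 19932 bp wide.

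Forebrain patterning transcription factors, a list fixed beforehand, had wide domains. All 32 forebrain patterning transcription factors were marked in the replicated list and in both replicates, against 65.0% of the other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 9.31e-06). The difference of 35 points was 9.38 against random lists matched on promoter CpG ratio. Random lists matched on the number of CpGs within 5000 bp of the outermost TSS had a median share of 93.8%. Against them the share did not pass the threshold (permutation test, adjusted p = 0.521). The central 95% of those lists reached 100%, so no share could have passed as higher. The test therefore cannot tell whether CpG number accounts for the marking. Their median domain was 10265 bp wide, against 1955 bp for all other marked genes (permutation test, adjusted p = 6e-05, which rests on the smallest p of 2e-05 that 100000 permutations can give). In the replicates' own lists their median was 10468 bp ± 2290 (SD, n = 2). The difference of 8309.5 bp from other marked genes was 4592.5 bp with unmerged peaks. Of the 32 genes, 27 were in the widest 5% of marked genes, among them Nr2f2, Foxg1 and Lhx2. The 5 outside it were Sim1 at 3246 bp, Gbx2 at 3240 bp, Rax at 1467 bp, Six6 at 583 bp and Hesx1 at 551 bp in the replicated list, named after their values were seen. Rax, Six6 and Hesx1, homeobox genes of the eye field and pituitary region, had peak signal values of 5.05, 5.25 and 5.88, against a median of 45 for all marked genes. The domain of Rax was wider in each replicate's own list, at 4223 and 2450 bp.

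Lists of ventral and dorsal telencephalon, progenitor and signalling centre genes had wide domains too. All 20 ventral telencephalon and GABAergic genes were marked (adjusted p = 0.000441, Fisher's exact test), with a median width of 6688 bp and Dlx1, Dlx2 and Dlx6 as the widest. Of the dorsal telencephalon and glutamatergic genes 19 of 20 were marked (adjusted p = 0.00546, Fisher's exact test). Their median width was 4522 bp, with Emx2, Lhx9 and Fezf2 as the widest. The 1 gene without a peak was Neurod6, a gene of differentiating cortical neurons. Emx2, Lhx9 and Fezf2 were also in the forebrain patterning list, so these lists are not independent. Widths without the shared genes were not tested. All 24 neural progenitor genes were marked, with a median width of 5570 bp, led by Sox2, the RNA-binding protein gene Msi1 at 11414 bp ± 177 (SD, n = 2) and Nr2e1 at 10338 bp ± 385. The Nr2e1 domain also covered the TSS of Ostm1. All 24 genes of the brain's signalling centres were marked, with a median of 4576 bp. Axin2, a target of Wnt signalling, was the widest at 9252 bp ± 53.7, followed by the hedgehog receptor gene Ptch1 at 9202 bp ± 2383 and Wnt5a at 7812 bp ± 82.7. The width of each of these 4 lists differed from that of other marked genes with adjusted p = 6e-05 (permutation test). The size of the ventral difference depended on the setting: it was 4732.5 bp in the replicated list, 2651 bp without replicate 2, 2361 bp with −log10 q of at least 10, 2495 bp among the 10691 replicated peaks of highest signal value, 2427 bp unmerged and 7976 bp merged at up to 3000 bp. The dorsal difference of 2567 bp was 1572 bp unmerged and 4418 bp merged at up to 3000 bp. All 24 postmitotic neuron genes were marked too. Their median width of 3119 bp exceeded that of other marked genes (adjusted p = 0.000103, permutation test), and the widest were the neuronal filament gene Ina, the tubulin gene Tubb3 and Insm1 at 6001 bp ± 100.4, 5249 bp ± 158 and 4875 bp ± 93.3. The Ina domain also covered the TSS of Nt5c2. Against random lists matched on promoter CpG ratio, the shares of the ventral list and of the signalling centre list no longer stood out (permutation test, adjusted p = 0.296 and 0.188), and the matched lists had a median of 95% and 91.7% marked. For both, the central 95% of the matched lists reached 100%, so no share could have passed as higher. The dorsal and progenitor differences of 30 and 35 points were 15 and 12.5 against these lists. Against lists matched on the number of CpGs the shares of the ventral, dorsal, progenitor and signalling lists did not pass (permutation test, adjusted p = 0.521, 1, 0.120 and 0.521). Here too the central 95% of the matched lists reached 100% for each, so these tests could not show an excess. Among the 10691 replicated peaks of highest signal value the differences in share were −0.958 points for ventral, −5.96 for dorsal, 3.21 for neuron and 15.7 for signalling genes, none past the threshold (Fisher's exact test, adjusted p = 1, 0.728, 0.881 and 0.179).

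**Figure D2:**
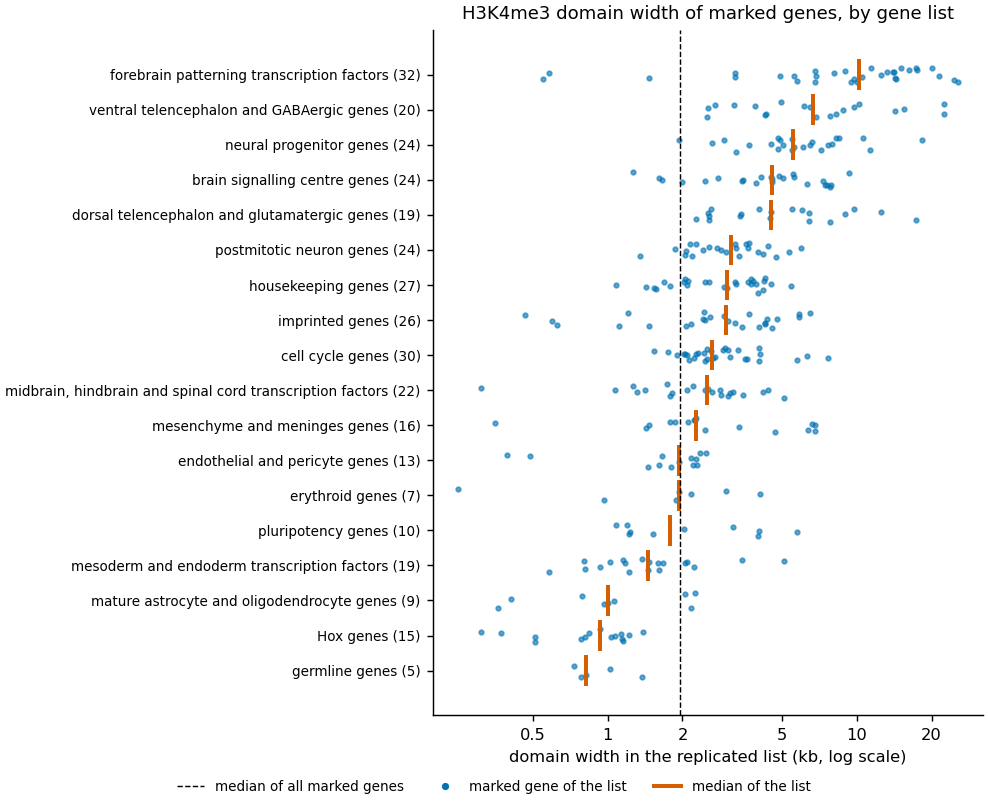
Domain width of marked genes in the replicated list, in kb on a log scale, for each gene list with at least 5 marked genes. Each point is a gene, the orange bar is the list's median, the dashed line is the median of all marked genes at 1957 bp, and the number in brackets counts marked genes. Medians ran from 823 bp for germline genes to 10265 bp for forebrain patterning transcription factors.

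Genes of mature glia had narrow domains where they were marked. Of 18 mature astrocyte and oligodendrocyte genes, 9 were marked (50%, also in each replicate's own list), a share for which no difference from other genes passed the threshold (adjusted p = 0.268, Fisher's exact test). Among the 10691 replicated peaks of highest signal value it was lower, with a difference of −28.8 points, (Fisher's exact test, adjusted p = 0.0227). The 9 marked genes had narrower domains than other genes, with a median of 1007 bp (adjusted p = 0.00439, permutation test). The glutamate transporter gene Slc1a2 had the widest at 2180 bp ± 161 (SD, n = 2) and the myelin gene Mbp had 2089 bp ± 263. The Mbp domain (chromosome 18, 82474720 to 82476887) covered the outermost TSS, at 82475146, of a gene that reaches 82585637. Its other annotated starts were not examined separately, so the peak need not lie at the start used in myelinating cells. Aqp4, Aspa and Gfap had no peak at any TSS.

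Transcription factors of the midbrain, hindbrain and spinal cord were marked more often than other genes, and the call depended on the setting. Of 24 genes, 22 were marked (91.7%, adjusted p = 0.00643, Fisher's exact test), with a median width of 2504 bp. The widest were Mafb at 5034 bp ± 86.3 (SD, n = 2), Lmx1a at 3843 bp ± 2727 and Lmx1b at 4088 bp ± 214. Phox2b had no peak, and Evx1 had one in replicate 1 only. Keeping peaks of at least 10 in −log10 q ended the call on the share (Fisher's exact test, adjusted p = 0.170), as did using each gene's outermost TSS (0.121), and lists matched on CpG ratio, whose median share was 87.5% (permutation test, 0.989), or on CpG number (1). The central 95% of the lists matched on CpG number reached 100%, so a higher share could not have passed against them. Among the 10691 replicated peaks of highest signal value the difference turned to −38.5 points (Fisher's exact test, adjusted p = 0.000257). The difference in width, of 548 bp (adjusted p = 0.0398, permutation test), was lost in replicate 1's own list (0.485), in the pooled list (0.0698), with −log10 q of at least 2 (0.247) or 10 (0.330) and with the outermost TSS (0.348). It turned to −22.5 bp with unmerged peaks and to −361 bp against lists matched on CpG number (0.924 and 0.304), and was 2073 bp merged at up to 3000 bp.

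Hox genes, which pattern the body axis behind the forebrain, were marked less often than other genes and with narrower domains. In the replicated list 15 of 39 were marked (38.5%, adjusted p = 0.00182, Fisher's exact test), with a median width of 934 bp against 1958 bp (adjusted p = 6e-05, permutation test). The marked genes included Hoxd8 at 1269 bp ± 139 (SD, n = 2), Hoxd1 at 1176 bp ± 28.3 and Hoxd9 at 1082 bp ± 173, while Hoxa10, Hoxa11 and Hoxa2 were not marked in that list. The cluster on chromosome 2 (Hoxd) held 7 marked genes of 9, Hoxa 5 of 11, Hoxb 2 of 10 and Hoxc 1 of 9. Hoxd3 and Hoxd4, named after their values were seen, shared 1 domain. Genes of a cluster are thus not independent, and the p-values of both tests, which treat them as such, may be too small. The 2 replicates' own lists marked more Hox genes, at 46.2% and 51.3%, and without replicate 1 the share no longer passed the threshold (Fisher's exact test, adjusted p = 0.085). It did not pass in the pooled list either (0.164). The difference of −26.6 points was −40.3 with −log10 q of at least 10, −48.5 among the 10691 replicated peaks of highest signal value, and −51.3 and −56.4 against lists matched on CpG ratio and CpG number. The difference in width of −1024 bp was −1827 bp against lists matched on CpG number.

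Transcription factors of mesoderm and endoderm were marked at 67.9%, and no difference from other genes passed the threshold (adjusted p = 0.887, Fisher's exact test). The share was lower among the 10691 replicated peaks of highest signal value (a difference of −43.9 points, Fisher's exact test, adjusted p = 3.34e-06) and against lists matched on CpG number (−25 points, permutation test, adjusted p = 0.0007). Their median width was 1460 bp (adjusted p = 0.04, permutation test), and the widest were Foxa1, Gata6 and Nr5a1 at 5045 bp ± 59.4 (SD, n = 2), 3266 bp ± 454 and 2284 bp ± 368. Cdx2, Hand1 and Hnf1a had no peak. The difference in width did not pass the threshold once genes with a shared domain were left out (permutation test, adjusted p = 0.0753) or against lists matched on CpG ratio (0.425), and turned to 68 bp with peaks merged at up to 3000 bp. It was −1175 bp against lists matched on CpG number, and −497 bp against other marked genes.

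Lists of other cell types that the dissected tissue could hold were each compared with all other genes. Of 20 macrophage and microglia genes only Irf8 and Fcgr3 were marked (10%, adjusted p = 3.61e-06, Fisher's exact test), and Aif1, C1qa and C1qb were not. Their difference of −55.1 points was −20 against lists matched on CpG ratio. Of 19 erythroid genes 7 were marked (36.8%, adjusted p = 0.019, Fisher's exact test), led by Tal1 at 4881 bp ± 17.0 (SD, n = 2), and none of the 7 globin genes was marked in any list. The erythroid share did not pass the threshold in replicate 2's own list, at 52.6% (Fisher's exact test, adjusted p = 0.276), or in the pooled list (0.0703). Lists matched on CpG ratio had a lower median share of 21.1%, which turned the difference to 15.8 points, and those matched on CpG number had 36.8% (permutation test, adjusted p = 0.296 and 1). Endothelial and pericyte genes were marked at 65% and mesenchyme and meninges genes at 80% (Fisher's exact test, adjusted p = 1 and 0.28). Among the 10691 replicated peaks of highest signal value the endothelial and mesenchyme shares were lower, with differences of −41 and −36 points (Fisher's exact test, adjusted p = 0.000333 and 0.00201). The median widths of marked erythroid, endothelial and mesenchyme genes, 1930, 1935 and 2260 bp, did not pass the permutation test (adjusted p = 0.954, 0.954 and 0.306). Marked endothelial genes included Kdr, Ets1 and Egfl7 at 2482 bp ± 159, 2313 bp ± 60.8 and 1691 bp ± 656, whereas Cdh5 and Pecam1 had no peak. The Egfl7 domain also covered the TSS of Gm20532. Among mesenchyme genes the homeobox genes Alx4 and Prrx1 and the forkhead gene Foxc1 had the widest domains, at 6764 bp ± 119, 6109 bp ± 1126 and 5030 bp ± 2255. The collagen gene Col3a1 had a peak in replicate 2 only. In replicate 2's own list the mesenchyme share was 90% and passed the threshold (Fisher's exact test, adjusted p = 0.0265).

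Genes of differentiated liver, muscle, pancreas and skin were marked at 15.4% (4 of 26, adjusted p = 2.79e-06, Fisher's exact test), and Alb, Apoa1 and Acta1 were not. The 4 were the skin gene Lor, the muscle gene Ckm and 2 members from outside the tissues in the list's name, the lung gene Sftpc and the kidney gene Nphs2, the last named after its values were seen, and replicate 1 marked neither Sftpc nor Lor. The Sftpc domain also covered the TSS of Bmp1, and that of Ckm covered the TSS of Klc3. Germline genes were marked at 20.8% (5 of 24, adjusted p = 4.22e-05, Fisher's exact test), with a median width of 823 bp (adjusted p = 0.00636, permutation test). The 5 were Brdt, Smc1b, Rec8, Dazl and Dmc1, of which Dazl and Dmc1 are named after their values were seen. The Brdt domain (chromosome 5, 107359286 to 107360662) did not cover that gene's outermost TSS at 107331159. The Smc1b domain also covered the TSS of Ribc2, and replicate 1 did not mark Dmc1. Pluripotency genes were marked at 55.6% (adjusted p = 0.508, Fisher's exact test), with a median width of 1779 bp (adjusted p = 0.651, permutation test). Their share was lower, with a difference of −28.8 points, among the 10691 replicated peaks of highest signal value (Fisher's exact test, adjusted p = 0.0227). Sall4, Klf4 and Lin28a had the widest domains of that list, at 5683 bp ± 108 (SD, n = 2), 3973 bp ± 10.6 and 3830 bp ± 841, and Dppa2, Dppa4 and Dppa5a had no peak. Of 1466 olfactory and vomeronasal receptor genes 3 were marked, namely Olfr94, Olfr658 and Vmn1r4, whose domain also covered the TSS of Nt5c3. The Olfr94 domain (chromosome 17, 37196680 to 37197887) did not cover that gene's outermost TSS at 37200994. Random lists matched on promoter CpG ratio had a median share of 13.3% (permutation test, adjusted p = 0.00105). The receptor difference of −69.5 points was −13.1 against those lists and −7.78 against lists matched on CpG number. The liver, muscle, pancreas and skin share did not pass the threshold against random lists matched on promoter CpG ratio (permutation test, adjusted p = 0.553), whose median share was 23.1%. It passed as lower against lists matched on CpG number, whose median share was 53.8% (−38.5 points, permutation test, adjusted p = 0.0007).

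All 27 housekeeping genes and all 30 cell cycle genes were marked (adjusted p = 4.70e-05 and 1.26e-05, Fisher's exact test). Their domains were 3019 and 2624 bp wide at the median (adjusted p = 0.000135 and 0.00491, permutation test). Among housekeeping genes Chmp2a, whose domain also covered the TSS of Ube2m, had the widest in the replicated list, at 5459 bp, but 3670 bp ± 3259 (SD, n = 2) over the replicates, and Tbp, which also shared its domain with Psmb1, had 4459 bp ± 41.0. The cyclin genes Ccnd2 and Ccnd1 and the ribonucleotide reductase gene Rrm2 had 7547 bp ± 33.2, 6326 bp ± 96.2 and 5533 bp ± 71.4. Of the imprinted genes 26 of 28 were marked (92.9%, adjusted p = 0.00182, Fisher's exact test), with a median width of 2992 bp (adjusted p = 0.0002, permutation test). Mest had the widest at 6969 bp ± 692, Peg3 and Usp29 shared a domain of 6008 bp ± 349, and Ddc and Ndn had no peak. The difference in width of imprinted genes was lost when each gene's outermost TSS was used (permutation test, adjusted p = 0.375), and that of imprinted and of housekeeping genes when only the 10691 replicated peaks of highest signal value were kept (0.0852 and 0.122). The imprinted difference of 1036.5 bp was 648 bp without replicate 2, 654 bp with −log10 q of at least 10, 461.5 bp unmerged and 1850 bp merged at up to 3000 bp, and the housekeeping difference of 1064 bp was 473.5 bp unmerged. The share of cell cycle genes did not pass against lists matched on CpG ratio (permutation test, adjusted p = 0.675), nor did those of housekeeping and imprinted genes against lists matched on CpG number (0.076 for each). For cell cycle genes the central 95% of the lists matched on CpG ratio reached 100%, so no share could have passed as higher. Other differences shrank but passed: against lists matched on CpG ratio housekeeping genes had 11.1 points in place of 35 and imprinted genes 17.9 in place of 27.9, and against lists matched on CpG number cell cycle genes had 13.3 in place of 35. The imprinted share turned to −15.3 points among the 10691 peaks of highest signal value (Fisher's exact test, adjusted p = 0.161).

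**Figure D3:**
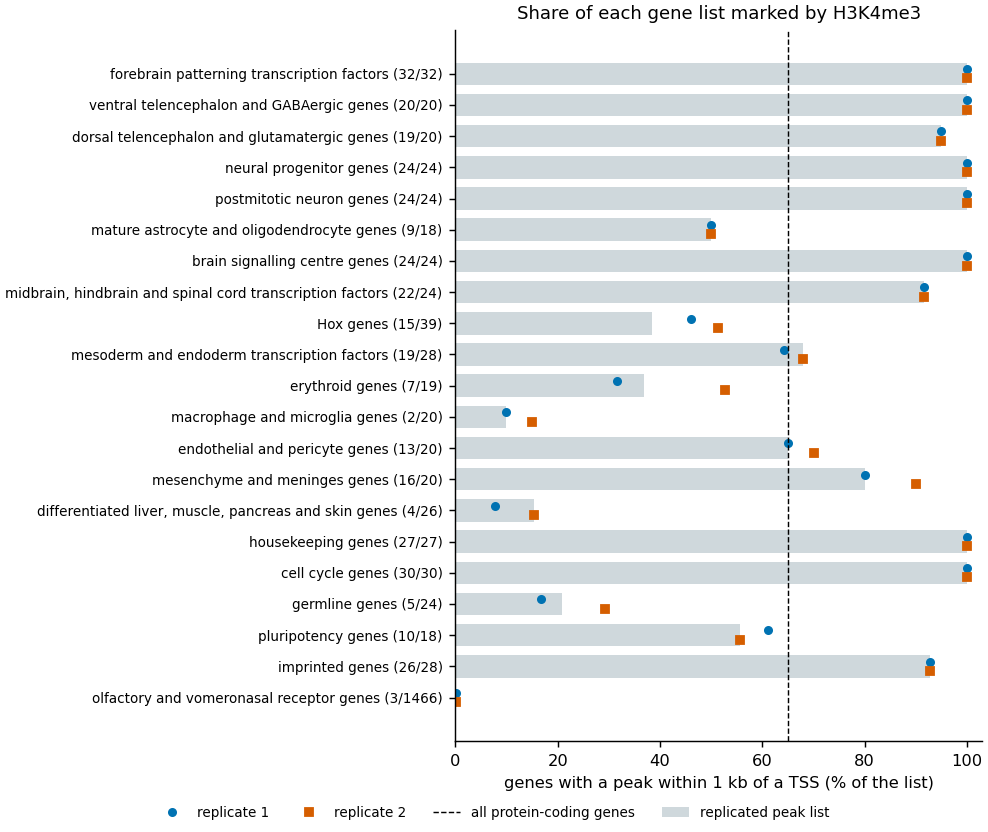
Share of each gene list with a peak within 1 kb of a TSS, in percent. Bars show the replicated list, circles replicate 1 and squares replicate 2, the dashed line is the share of all protein-coding genes at 65.0%, and brackets give marked over all genes. Forebrain, progenitor, neuron, housekeeping and cell cycle lists reached 100%, whereas receptor genes were at 0.205%.

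Width and height of the mark did not rank the lists alike. The height of a gene is the highest of the authors' signal values among peaks at its TSSs, whose scale is not given in the sources used here. Housekeeping genes had a median height of 63.3 against 45 for other marked genes (adjusted p = 0.000216, permutation test). Forebrain patterning transcription factors had 37.0, and neural progenitor genes 54.1, and neither passed the permutation test (adjusted p = 0.120 and 0.0848). Ventral and dorsal telencephalon genes were lower, at 24.3 and 24.1 (permutation test, adjusted p = 0.00338 and 0.00504), as were postmitotic neuron genes at 28.9 (adjusted p = 0.00978) and imprinted genes at 21.3 (adjusted p = 0.000216). Transcription factors of the midbrain, hindbrain and spinal cord, of mesoderm and endoderm, and Hox genes had 15.5, 9.55 and 8.37 (permutation test, adjusted p = 0.00012 for each). Marked endothelial, mesenchyme, erythroid, germline, mature glial and pluripotency genes were lower too, at 13, 17, 10, 7.1, 15.8 and 24.6 (permutation test, adjusted p = 0.000411, 0.000411, 0.00188, 0.00188, 0.00579 and 0.0324). Against lists matched on CpG ratio the lower heights of neuron, erythroid and pluripotency genes did not pass (permutation test, adjusted p = 0.0517, 0.0517 and 0.0528). Against lists matched on CpG number, forebrain patterning factors and signalling centre genes passed as lower, with differences of −13.4 and −16.2 (permutation test, adjusted p = 0.0203 and 0.00997). Without replicate 2 ventral, dorsal and erythroid genes were lower too, with differences of −13.6, −12.9 and −23.0 (permutation test, adjusted p = 0.00909, 0.0149 and 0.00574). These are in the units of replicate 1's own list, where the median height of marked genes was 32.3, so their sizes are not compared with −20.7, −20.8 and −35 in the replicated list. Of the 18 lists tested, 2 were higher and 13 lower. The higher value of cell cycle genes, 54.8 (permutation test, adjusted p = 0.0397), did not pass in either replicate's own list (0.0668 and 0.0529) or against lists matched on CpG ratio (0.0715). Neural progenitor genes passed as higher in both replicates' own lists (permutation test, adjusted p = 0.00909 and 0.0225). Against lists matched on CpG ratio or CpG number they did not (permutation test, adjusted p = 0.140 and 0.283). Signalling centre genes, at 33 with adjusted p = 0.050 in the replicated list, passed as lower in both replicates' own lists (permutation test, adjusted p = 0.0202 and 0.0279).

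Marking rose with the CpG content at a gene's outermost TSS. A gene could be marked at any of its TSSs, so the ratio need not be that of the marked promoter. In quintiles of the observed to expected CpG ratio within 500 bp of the outermost TSS, 8.93% ± 0.483 (SD, n = 2), 31.7% ± 1.84, 87.5% ± 0.516, 98.3% ± 0.21 and 99.4% ± 0.0806 of genes were marked, from the lowest to the highest. The median width of marked genes was 1586, 1435, 1547, 1957 and 2400 bp in the same order.

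Peaks away from promoters were fewer, narrower and lower. In the replicated list 2869 peaks (13.4%) lay over 5000 bp from every annotated TSS, with a median width of 577 bp and a median signal value of 6.08. Of these, 62.2% were intergenic, 26.3% in introns and 11.5% in exons. The share was 14.3% ± 2.76 (SD, n = 2) in the replicates' own lists. The peak of highest signal value among them, 61.1, was intergenic on chromosome 9 (32031560 to 32033912), 10946 bp from the pseudogene Gm47481 and 82224 bp from Arhgap32. The next lay on chromosome 2 (166785754 to 166787244), 5287 bp from Trp53rkb, at 56.7, and on chromosome 14 (76151797 to 76153740), 40906 bp from Nufip1, at 51.9. A peak at 51.9 on chromosome 4 (46304624 to 46305605) lay in an intron of Gm12446, 38004 bp from the forkhead gene Foxe1, and one at 51.3 on chromosome 9 (67632054 to 67634768) lay 72351 bp from Tln2. All 5 overlapped a peak of each replicate. Peaks of at least 10 in −log10 q left 1547, and the 10691 peaks of highest signal value left 160.

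The 2 replicates marked nearly the same genes with domains of like width. Of 21938 protein-coding genes, 14143 were marked in both replicates and 7497 in neither, so 98.6% had the same call. Across the genes marked in both, domain widths had a Spearman's rho of 0.925 and a Pearson's r of 0.924, over genes, which are not independent replicates. Domains were wider in replicate 2 for 77.2% of these genes, with a median ratio of 1.09. Peaks overlapped less than genes: 92.7% of replicate 1 peaks shared at least 1 bp with a replicate 2 peak, and 76.8% of replicate 2 peaks with a replicate 1 peak, against 2.67% and 2.42% with shuffled peaks. With an overlap of 50% of both peaks the first share was 74.6%. The Jaccard index of covered bases was 79.7%. Peaks without a partner numbered 1741 in replicate 1 and 6053 in replicate 2, and had median widths of 224 and 253 bp.

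**Figure D4:**
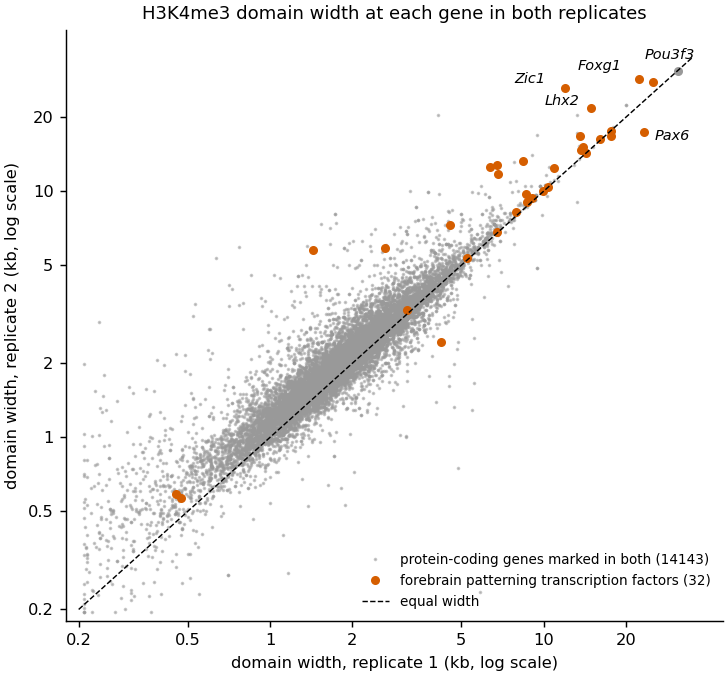
Domain width in kb at each protein-coding gene marked in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both on a log scale. Grey points are genes, orange points the 32 forebrain patterning transcription factors, and the dashed line marks equal width. Pou3f3 is at 30820 and 30620 bp, and the orange points lie mostly at the upper right, with Zic1 farther above the line than Foxg1.

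Genes marked in one replicate only numbered 52 in replicate 1 and 246 in replicate 2. The highest in replicate 1 were Bricd5 and Igfn1, with signal values of 49.1 and 12.8, followed by S1pr5 at 4.53 and by Lbhd2 and Gm7102, which tied with others at 4.3. The highest in replicate 2 were Sftpc, Mvp, Lor, Clec11a and 1700017N19Rik, with signal values of 66.1, 57.7, 51.7, 49.2 and 48.5. In the replicated list the domain of Bricd5 also covered the TSSs of E4f1 and Pgp, and that of Igfn1 the TSS of Tmem9. The Sftpc domain there covered the TSS of Bmp1, and that of 1700017N19Rik the TSS of 4930430F08Rik. Mvp had a domain of 230 bp in the replicated list and of 3971 bp in replicate 2's own list. The peaks behind Bricd5, Igfn1 and those 5 replicate 2 genes did overlap a peak of the other replicate, which ended outside the 1000 bp window of the gene. Of the 52 and 246 genes, 3 and 14 were of this kind. The other 49 and 232 had no overlapping peak in the other replicate, with median signal values of 3.23 and 3.9.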

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

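The main comparisons used the 21 chromosomes, and 11 replicated peaks lay outside them, on 6 scaffolds, where a peak was not part of any comparison with genes. Their median signal value was 7.54, and 9 of the 11 overlapped a peak of both replicates. No explanation was tested.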

How the results depend on the processing

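Lists matched on CpG number were chosen after the data were seen, and all other alternatives before. Of the settings of gene list shares, 188 kept direction and side of the threshold, 22 weakened, 4 strengthened and 17 reversed. For widths 214 kept both, 10 weakened and 15 reversed, and for heights 76 kept both, 6 weakened and 7 strengthened. The unknown depth of the libraries limits what an absent peak can show. The cause of each change below was not tested, and values are differences from other genes in percentage points, bp or the signal units of the peak list used.

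With −log10 q of at least 2, the endothelial share was 0.0899 and the widths of midbrain, hindbrain and spinal cord factors and of erythroid genes 311 and 96. With at least 10, the shares of midbrain to spinal cord and of mesoderm and endoderm factors were 15.9 and −6.19, and the width of the former 265. With the 50% of peaks of highest signal value, shares were −0.958 for ventral, −5.96 for dorsal, 3.21 for neuron, −28.8 for mature glial, 15.7 for signalling, −38.5 for midbrain to spinal cord, −43.9 for mesoderm and endoderm, −41.0 for endothelial, −36.0 for mesenchyme, −28.8 for pluripotency and −15.3 for imprinted genes. Widths were 286 for housekeeping and 584.5 for imprinted genes.

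With a TSS window of 500 bp, the endothelial share was 0.377 and the erythroid width 91. With the outermost TSS, shares were 17.8 for midbrain to spinal cord and −4.23 for mesoderm and endoderm, and widths 257 for midbrain to spinal cord, 668 for pluripotency and 217 for imprinted genes. In the pooled list, the Hox and erythroid shares were −11.6 and −23.3, and the widths of midbrain to spinal cord and erythroid genes 492 and 51.5. Unmerged peaks gave midbrain to spinal cord −22.5 in width. Merging at up to 3000 bp gave mesoderm and endoderm 68 and endothelial genes 138. Without shared domains these were −398 and 49, and erythroid genes 115.

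Over the lists without replicate 1 or without replicate 2, shares ranged from −18.6 to −14.3 for Hox, −0.42 to 2.27 for mesoderm and endoderm, −33.2 to −13.0 for erythroid, 0.295 to 4.41 for endothelial and 15.3 to 24.4 for mesenchyme genes. The width of midbrain to spinal cord factors ranged from 189 to 584.5. Heights ranged from 10.7 to 11.7 for progenitor, −14.1 to −10.6 for signalling and 6.80 to 9.21 for cell cycle genes, and the percent of peaks at a TSS from 67.3 to 73.1.

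Against lists matched on CpG ratio, shares differed by 5 for ventral, 8.33 for signalling, 4.17 for midbrain to spinal cord, −7.14 for mesoderm and endoderm, 15.8 for erythroid, 10 for endothelial, −7.69 for liver, muscle, pancreas and skin and 3.33 for cell cycle genes. Widths differed by −187.5 for mesoderm and endoderm, 327 for erythroid and 259 for endothelial genes. Heights differed by −12.4 for neuron, −12.3 for signalling, −21.6 for erythroid, 7.46 for cell cycle and −17.1 for pluripotency genes. Against lists matched on CpG number, shares differed by 6.25 for forebrain patterning factors, 5 for ventral, 0 for dorsal, 8.33 for progenitor, 4.17 for signalling, 0 for midbrain to spinal cord, −25 for mesoderm and endoderm, 0 for erythroid, 11.1 for housekeeping and 14.3 for imprinted genes. Widths differed by −361 for midbrain to spinal cord, 210.5 for erythroid, 25 for endothelial and −258 for mesenchyme genes, and heights by −13.4 for forebrain patterning factors and −16.2 for signalling genes.

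Peaks with −log10 q of at least 10 numbered 15656 and 17278 in replicates 1 and 2. The 50% of highest signal value held 11965, 13044, 11923 and 10691 peaks in replicate 1, replicate 2, the pooled and the replicated list, and 90.5% of such replicate 2 peaks had a partner. With 50% of both peaks shared, 74.6% of replicate 1 peaks had one. The percent of peaks at a TSS was 85.4 with −log10 q of at least 10, 97.7 for the highest 50%, 80.3 with a window of 2000 bp, 65.0 with the outermost TSS and 71.1 in the pooled list. The percent of genes marked was 63.3, 51.0, 65.7 and 61.4 under the first 4 of these. Distal peaks numbered 1547 and 160 under the first 2, and 5215 at over 1000 bp. In the lowest CpG quintile within 1000 bp, 6.91% of genes were marked. The widths of forebrain patterning, ventral, dorsal, progenitor, signalling, neuron and Hox genes kept their call under each setting that gave a value, though the sizes of some differences moved. A list with under 5 marked genes under a setting has no width or height there.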

Other observations

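The tests of blood and mesenchymal cells, and the use against each list alone of CpG number and of the planned lists matched on CpG ratio, were chosen only after the result was seen, and the test of forebrain widths against CpG number after the widths but before its matched values were seen. Width and height of the mark were only partly related. Across marked genes, width and signal value had a Spearman's rho of 0.513, over genes, which are not independent replicates. Of the genes in the widest 5%, 36.8% had a signal value below the median of all marked genes. Among all marked members of a list, whatever their width, 95.8% of the postmitotic neuron genes, 95% of the ventral telencephalon genes and 92.3% of the imprinted genes lay below that median, against 16.7% of the cell cycle genes and 25.9% of the housekeeping genes. All 22 marked transcription factors of the midbrain, hindbrain and spinal cord lay below the median. So did all marked Hox, erythroid, macrophage and microglia, endothelial, mesenchyme, germline, pluripotency and receptor genes.

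The wide domains at the 32 forebrain patterning transcription factors were not matched by other genes in the same deciles of CpG content at the outermost TSS. Their median of 10265 bp exceeded that of 100% of 10000 random lists matched on promoter CpG ratio, whose median was 1881 bp, and of 100% of those matched on the number of CpGs within 5000 bp, whose median was 2905 bp. Domains such as that of Foxg1, 24687 bp wide, reached beyond these windows, so CpG content over whole domains was not matched. The difference from other marked genes was 8309.5 bp with merging and 4592.5 bp with unmerged peaks, so merging adds to it and is not the whole of it. With 1 TSS per gene it was 100.1% of that with all TSSs. No biological explanation was tested.

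The 3 lists of Hox genes, midbrain to spinal cord factors and mesoderm and endoderm factors were together marked at 61.5%. They are named for other regions and germ layers, but whether their members are also expressed in the forebrain was not tested. Random lists matched on CpG ratio had 84.6%, with a central 95% of 79.1% to 90.1%, so the lists were marked less than their CpG content would give, and the bound set beforehand, a share outside that range, was wrong to count a lower share against CpG content. Hox genes at 38.5% lay below the ranges for CpG ratio and CpG number, 82.1% to 97.4% and 89.7% to 100%, and mesoderm and endoderm factors at 67.9% only below that for CpG number, 82.1% to 100%. Midbrain to spinal cord factors at 91.7% lay within both, 79.2% to 95.8% and 83.3% to 100%, the last with no room above it. CpG content may account for their marking, and it stays open for the others. Blood and mesenchymal cells also stay open, since a missing peak excludes nothing and the bound of at most 1 in 4, which the globin genes met, was wrong: 0 of 7 globin genes (0%) and 2 of 6 matrix genes (33.3%) were marked in both replicates, while erythroid genes were marked at 31.6% in replicate 1 and 52.6% in replicate 2.

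Peaks found in one replicate only were narrow and weak, with a median −log10 q of 2.17 in replicate 1 and 2.79 in replicate 2, against 50.1 and 125 for peaks with a partner. Of peaks with −log10 q of at least 10, 100% in replicate 1 and 98.9% in replicate 2 had a partner. These values met the bounds set beforehand for peaks near the calling threshold. That threshold is not given, and the 2 lists held peaks down to a −log10 q of 0.353 and 0.156. The values therefore show that unpartnered peaks were weak, not how near the threshold they lay. The splitting of one domain into different pieces stays open. Of the unpartnered peaks of both replicates, 48.9% lay within 1000 bp of a peak of the other. The share was 57.4% in replicate 1, above the bound of 50% set beforehand, and 46.5% in replicate 2, below it. The depth of the libraries was not known, and no biological explanation was tested.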
